A study of Mus musculus with 14 samples.

How the data were processed

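RNA from 3 mouse tumour cell lines was sequenced after exposure to a RIG-I agonist or a control agonist. The lines were CT26, a BALB/c colorectal carcinoma, E0771, a C57BL/6 mammary carcinoma, and MC38, a C57BL/6 colon adenocarcinoma. Per the labels, 100000 cells were plated per well and given 0.5 ug/ml of either agonist, and RNA was taken 24 h later. Poly(A)-containing RNA was made into stranded libraries for Illumina sequencing. There were 3 libraries per agonist in CT26 and 2 per agonist in E0771 and in MC38, 14 in all, and the groups and replicate numbers were taken from the sample titles. No untreated cells were analysed here, so every fold change is relative to the control agonist.

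The authors deposited 3 tables, one per line, of estimated counts per gene for 34866 Ensembl gene identifiers. The submitters' processing notes name Salmon, DESeq2 and the GRCm38 genome build, without their roles. The annotation the authors used, any read trimming and the software versions were not given in the sources used here. Each estimated count was rounded to a whole number before testing. Between 69.1% and 85.3% of the deposited values per library, zeros included, were exactly whole, with no tolerance. Each column matched 1 sample by the name in that sample's labels, and in MC38, where the columns carry other numbers than the titles, by the column name the labels state. The gene identifiers were matched to the GENCODE M21 annotation of GRCm38 for symbols, biotypes and positions: 32574 matched exactly, 34582 after the version suffix was dropped, and 284 had no name. The table held 21782 protein-coding and 12298 pseudogene identifiers and 28 long non-coding ones, so nearly all long non-coding genes lay outside the measurement, and 52 symbols stood for more than 1 identifier. Positions are 1-based.

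Estimated counts divide reads shared by near-identical genes. Values for the Ifna, Gbp, Tgtp, Ifi200, Raet1 and H2 families are therefore uncertain for single members, and pseudogenes can hold reads of their parent genes. CT26 comes from BALB/c mice and the reference is C57BL/6, so alleles of H2 and of other polymorphic genes can be counted less completely in CT26 in both agonist groups.

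Total counts per library were 32826742 to 40564102 in CT26, 12413347 to 13399247 in E0771 and 12347361 to 18964563 in MC38. A count of 0 allows a level of up to 3 counts, which was 0.074 to 0.091 counts-per-million (CPM) per library in CT26, 0.224 to 0.242 in E0771 and 0.158 to 0.243 in MC38. Over a group of libraries the same floor was 0.0262, 0.12 and 0.105 CPM. Where all controls were at 0, a fold is given as a lower bound from 3 counts over the control group. Where the controls held 1 to 3 counts together, the ratio of counts is given with its exact 95% interval. Floors and intervals cover counting error only.

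Within each line, RIG-I agonist was compared with control agonist by edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) with robust dispersions, TMM normalization, the filterByExpr filter at a minimum count of 10 and Benjamini-Hochberg adjustment over all genes tested. An adjusted p under 0.05 was called. Levels are CPM on TMM-scaled library sizes, given as mean and SD over libraries, and log2 fold changes carry their standard error. The fitted fold changes use a prior count of 0.125. Differences between lines were tested as interactions in 1 edgeR fit of all 14 libraries with 6 groups. That fit has 1 shared estimate of the spread, with a common dispersion of 0.0149, against 0.041 in E0771 alone and 0.000927 in MC38 alone. Its p-values can therefore be too small for effects in E0771 and too large for effects in MC38. Normalization and filter over all 14 libraries also let its effects differ slightly from those of the fits per line.

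Of 27 gene lists, those with at least 3 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists. Camera was also run with the correlation estimated from the data, and fry was run as a test of whether a list moved one way on balance. The run with an estimated correlation also took its degrees of freedom from the residuals of the fit. Within a line these were 4 in CT26 and 2 in E0771 and in MC38. Its p-values can therefore be larger even where the estimated correlation is not above 0.01. The lists covered RNA sensing, type I and III interferons, interferon receptors with JAK, STAT, IRF and SOCS genes, antiviral interferon-stimulated genes, interferon-inducible GTPases, cytosolic DNA sensing, MHC class I, MHC class II, chemokines, cytokines and NF-kB targets, checkpoint ligands, NK cell receptor ligands, programmed cell death, p53 targets, cell cycle, MYC and ribosome biogenesis, ER stress, cholesterol biosynthesis, nuclear-encoded oxidative phosphorylation, glycolysis and hypoxia, extracellular matrix, epithelial genes, leukocyte markers, endothelial markers, immediate early genes, heat shock genes and mitochondrially encoded genes. They held 636 memberships, of which 4 matched no gene of the tables.

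The designs, the alternatives and the rule for named genes were chosen before the data were examined. The rule took 23 fixed genes in every line. It added the 8 called genes with the largest change in each direction among named genes at a mean log2 CPM of at least 1 whose groups did not overlap, up to 4 called members of each list by size of change (or the member with the smallest p), and the 5 genes with the largest difference in each direction for each pair of lines. Many of the genes it took are not reported here, and those named were picked from them after their values were seen, often because their calls held under the alternatives. Called members that moved against the direction of their list are named as well, and other genes named outside this rule are said to be so.

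The alternatives were RLE size factors, DESeq2 1.42.0, no filter, a filter at a minimum count of 50, the replicate number as a block, all 14 libraries in 1 fit, each library left out in turn, and for lists the estimated correlation and fry. Leaving out mitochondrially encoded genes, leaving out each library in the list tests, and the block together with the estimated correlation were added after the data were seen. Adjusted p values that DESeq2 gave as NA were left out.

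The steps were tested on simulated data drawn from the real means, library sizes and spread, with 200 changed genes. In the CT26 design, edgeR recovered 73.1% of genes changed 1.5-fold, 80.6% at 2-fold and 95.5% at 4-fold, and 11 of 177 calls were false. The E0771 design recovered 7.5%, 23.9% and 81.8%, with 20 of 95 calls false. The MC38 design recovered 85.1%, 89.6% and 92.4%, with 29 of 207 calls false. The false share in these simulations was therefore above the 5% aimed at in all 3 designs. DESeq2 gave 22 false calls of 190, 25 of 109 and 5 of 163. Interaction tests recovered 50.5% of 2-fold differences between CT26 and E0771 with 3 false calls and 52% between CT26 and MC38 with 6 false calls. E0771 and MC38 were simulated without a difference and gave 0 calls. These libraries were drawn with 1 spread per gene for all lines. False calls from unequal spread between lines could therefore not appear. A list raised 1.5-fold was called in all 3 designs, and 0 of 20 unchanged lists were called. Those lists held randomly picked genes simulated independently of each other. They therefore do not check the list tests where members are correlated. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.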

Results

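The transcriptomes of CT26, E0771 and MC38 cells were measured by poly(A) RNA sequencing 24 h after 0.5 ug/ml of a RIG-I agonist or a control agonist. RIG-I is the cytosolic sensor of viral RNA that starts type I interferon production, and the study concerns its activation within tumour cells. CT26 had 3 libraries per agonist with totals of 32826742 to 40564102 counts. E0771 had 2 per agonist with 12413347 to 13399247 counts, and MC38 had 2 per agonist with 12347361 to 18964563. Protein-coding genes held 92.69% to 97.84% of the counts, and the 10 most abundant genes held 4.56% to 7.92%. Replicates differed by more than sampling noise everywhere: the chi-square per degree of freedom was 7.8 to 31.85 in CT26, 39.83 and 43.8 in the E0771 groups, and 2.24 and 2.41 in the MC38 groups. This value also grows with depth, so the deeper CT26 libraries cannot be compared with the other lines by it. Error in dividing shared reads can add to it as well. The biological coefficient of variation fitted by edgeR was 0.102 in CT26, 0.202 in E0771 and 0.03 in MC38. Nothing in the labels says that replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. All adjusted p-values of genes are from edgeR's quasi-likelihood test, those of lists are from camera, and levels are mean ± SD in CPM.

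Positions of the fixed genes are given on GRCm38. Ifnb1 (ENSMUSG00000048806.4) lies on chromosome 4 at 88522025 to 88522774, close to Ifna4 at 88841861 to 88842421. Ddx58 (ENSMUSG00000040296.15), which encodes RIG-I, spans 40203773 to 40239828 and Isg15 156199424 to 156200818 on the same chromosome. Ifih1, which encodes the RNA sensor MDA5, lies on chromosome 2 at 62595798 to 62646255, and Dhx58, which encodes their relative LGP2, on chromosome 11 at 100694884 to 100704271. Zbp1 is on chromosome 2 at 173206612 to 173218923, Irf7 on chromosome 7 at 141262706 to 141266481 and Ifit1 on chromosome 19 at 34640871 to 34650009. Cxcl10 is on chromosome 5 at 92346638 to 92348889 and Ccl5 on chromosome 11 at 83525778 to 83530518. H2-K1 (33996017 to 34000347), Tap1 (34187553 to 34197225) and H2-D1 (35262730 to 35267499) lie on chromosome 17, B2m on chromosome 2 at 122147686 to 122153083 and Nlrc5 on chromosome 8 at 94434356 to 94527272. Cd274 spans 29367455 to 29388095 on chromosome 19.

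In CT26, the RIG-I agonist was followed by high levels of type I interferon, chemokine and antiviral transcripts (n = 3 libraries per agonist). Ifnb1, the gene of interferon beta, rose from 0.138 ± 0.108 to 110 ± 3.09 CPM, a log2 fold change of 9.58 (SE 0.17, adjusted p = 2.75e-13). Ccl5 and Cxcl10, chemokines that attract T cells, rose 86.8-fold (log2 6.44, SE 0.1, adjusted p = 1.92e-14) and 44-fold (from 11.1 ± 0.115 to 489 ± 11.3 CPM, adjusted p = 2.7e-15). Cd274, which encodes PD-L1, rose 8.42-fold from 5.83 ± 0.221 to 49.1 ± 1.76 CPM (adjusted p = 5.92e-13). Of 13893 genes tested, 2751 were higher and 2583 lower with the RIG-I agonist. At least a 2-fold change was seen for 868 higher and 59 lower genes, and the median called change was 0.51 up and -0.32 down on the log2 scale. In 5253 of the 5334 called genes the libraries of the 2 groups did not overlap. Over all genes tested this held for 51.4%, where chance gives 10%.

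All 4 measured interferon genes of CT26 rose, also adjusted over the list alone, with a median log2 fold change of 8.54, or 7.05 with the bounded members at their bound (adjusted p = 3.1e-29). Ifna4 went from 1 to 2220 counts, a ratio of 2320 with a counting interval of 417 to 91800. Ifna2 and Ifna13 had no control counts and were at least 23-fold and 21.4-fold higher. Members of this family share reads. Of 16 RNA-sensing genes, 12 rose and 1, the adaptor gene Mavs (-0.19), fell, with the same counts adjusted over the list alone (median 0.94, adjusted p = 9.74e-29). Zbp1, a sensor of Z-form nucleic acids, rose from 47 ± 2.72 to 513 ± 11.6 CPM (log2 3.45), Irf7, a transcription factor of interferon genes, by 2.51, Ifih1 by 2.26, Dhx58 by 2.35 and Ddx58 by 1.44 (SE 0.07, adjusted p = 5.22e-10). Of 19 receptor, JAK, STAT, IRF and SOCS genes, 12 rose and 1, Ifnar1 (-0.19), fell, again the same adjusted over the list alone (median 0.54, adjusted p = 7.24e-13). Irf5 rose by 4.13, Stat2 by 2.22 and the feedback inhibitor Usp18 by 2.15.

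All 56 antiviral interferon-stimulated genes measured in CT26 rose, also adjusted over the list alone, with a median log2 fold change of 1.83 (adjusted p = 1.07e-206). Their median level went from 71 to 256 CPM. Ifit1bl1 rose by 5.56, Mx1, a GTPase that blocks virus replication, by 4.78, Rsad2, which encodes viperin, by 4.03, Ifit1 by 3.07 and Isg15, a ubiquitin-like modifier, by 2.15. All 18 interferon-inducible GTPases rose on both adjustments (median 2.77, adjusted p = 1.29e-134), with Gbp5 at 3.92, Gbp2b at 3.65 and Iigp1 at 3.33. Of 10 cytosolic DNA-sensing genes, 8 rose on both adjustments (median 1.52, adjusted p = 1.03e-21), among them Ifi205 at 3.49 and the exonuclease gene Trex1 at 2.78.

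Of 26 MHC class I genes in CT26, 24 rose and 1, the chaperone gene Canx (-0.22), fell, the same adjusted over the list alone (median 1.44, adjusted p = 7.09e-61). H2-K1 rose from 429 ± 5.89 to 1100 ± 14.5 CPM (log2 1.36), H2-D1 by 1.12, the light chain gene B2m by 0.94, the peptide transporter gene Tap1 by 2.01, the class I transactivator gene Nlrc5 by 1.70 and the immunoproteasome gene Psmb9 by 2.44. Of 3 MHC class II genes, 2 rose, or 3 adjusted over the list alone (median 1.2, adjusted p = 0.126). Of 13 chemokine genes, 11 rose and 1, Ccl9 (-0.47), fell on both adjustments (median 4.62, adjusted p = 1.94e-61). Ccl4 rose by 8.81 (SE 0.18) and Cxcl1, which attracts neutrophils, by 5.89. Of 33 cytokine and NF-kB target genes, 23 rose on both adjustments (median 0.65, adjusted p = 3.91e-17), led by Il6 at 6.32 and Tnfsf10, which encodes the death ligand TRAIL, at 4.86. Of 11 checkpoint ligand genes, 6 rose, or 7 adjusted over the list alone, and 2, Vtcn1 (-1.03) and Tnfsf9 (-0.34), fell (median 0.54, adjusted p = 5.53e-05). Of 5 NK cell receptor ligand genes, 1, Clec2d (1.79), rose and 2, Ulbp1 (-0.69) and Cadm1 (-0.58), fell on both adjustments. The median was -0.17, the mean 0.09 and the adjusted p = 0.816.

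Cell death, immediate early and metabolic genes were also measured in CT26. Of 34 cell death genes, 16 rose, or 17 adjusted over the list alone, and 6 fell (median 0.22, adjusted p = 0.0092, and adjusted p = 0.0685 with an estimated correlation). Risers included Casp4, a caspase that cleaves gasdermin D, at 1.80 and Mlkl, the effector of necroptosis, at 1.07. The apoptosis inhibitor genes Xiap and Bcl2l1 and the caspase gene Casp6 were among those that fell. Casp8 rose by 0.31. Of 17 immediate early genes, 13 rose and 1, Klf2 (-0.71), fell on both adjustments (median 1.01, adjusted p = 2.16e-19), with Fos at 3.28 and Egr1 at 2.70. Of 22 glycolysis and hypoxia genes, none rose and 19 fell, or 20 adjusted over the list alone (median -0.52, adjusted p = 1.12e-07, and adjusted p = 0.216 with an estimated correlation). Pdk1, which encodes a pyruvate dehydrogenase kinase, fell from 143 ± 15.8 to 64.3 ± 4.41 CPM (log2 -1.15), the mitophagy gene Bnip3 by 0.87 and Gapdh by 0.43. Car9, a carbonic anhydrase gene induced by hypoxia, was at 13 ± 5.4 and 3.55 ± 0.956 CPM (log2 -1.88, adjusted p = 0.0367), and was not called without RIG-I replicate 1, 2 or 3 (adjusted p = 0.128, 0.122 and 0.0841) or control replicate 1 or 3 (0.0891 and 0.0906). Of 32 nuclear-encoded oxidative phosphorylation genes, 15 fell, or 16 adjusted over the list alone, and 1, Cycs (0.27), rose (median -0.13, adjusted p = 0.0192, and adjusted p = 0.645 with an estimated correlation).

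The remaining 11 lists did not pass in CT26. Of 40 cell cycle genes, 2 rose and 11 fell on both adjustments (median -0.05, adjusted p = 0.186). The proliferation marker gene Mki67 fell by 0.21 (adjusted p = 0.0123, and 0.0532 or 0.0512 without RIG-I or control replicate 2) and Ccnb2 by 0.44. Of 21 p53 targets, 8 rose, or 9 adjusted over the list alone, and 4 fell (0.10, adjusted p = 0.241). Btg2 rose by 2.01 and Cdkn1a was at 0.14 (adjusted p = 0.052). MYC and ribosome biogenesis had 9 higher and 2 lower of 26 on both adjustments (0.08, adjusted p = 0.497), with Myc at 0.50. ER stress had 15 higher and 10 lower of 29, or 15 and 11 adjusted over the list alone (0.17, adjusted p = 0.55). Atf3, a stress-induced transcription factor gene, rose by 4.81 and Ddit3 by 0.85. Cholesterol biosynthesis had 4 higher and 3 lower of 23 on both adjustments, and its median of 0.02 and the direction of its test differed in sign (adjusted p = 0.86). Extracellular matrix had 6 higher and 11 lower of 24, or 7 and 12 adjusted over the list alone (-0.17, adjusted p = 0.497), with Fn1, the fibronectin gene, at -0.79. Heat shock had 3 higher and 1 lower of 10 on both adjustments (0.14, adjusted p = 0.567). The 13 mitochondrially encoded genes had 3 higher and 1 lower on both adjustments. The median was -0.12, the mean 0.06 and the test pointed down (adjusted p = 0.86), and the mitochondrial share of counts was 2.44% to 2.88% with control and 2.85% to 3.19% with RIG-I agonist. Of 6 epithelial genes, 2 rose and 1 fell on both adjustments (0.36, adjusted p = 0.816). Of 6 leukocyte markers, 2 rose, or 3 adjusted over the list alone (0.48, adjusted p = 0.567), among them Fcgr1 from 2 to 41 counts, a ratio of 21.5 with an interval of 5.57 to 183. Of 3 endothelial markers, 1, Kdr, rose on both adjustments, from 1 to 108 counts, a ratio of 113 with an interval of 19.9 to 4510 (0.55, adjusted p = 0.206).

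Beyond the lists, Acod1, which makes itaconate, and Krt16, a stress keratin gene, were among the genes with the largest rises in CT26. Acod1 went from 1 to 1634 counts, a ratio of 1710 with an interval of 307 to 67600, and Krt16 from 1 to 1565, a ratio of 1640 with an interval of 294 to 64800. Ccrl2, an atypical chemokine receptor gene, rose from 0.113 ± 0.0101 to 10.9 ± 0.351 CPM (log2 6.55). Among genes at a mean log2 CPM of at least 1, the largest falls apart from Car9 and Pdk1 were those of Ifi27, from 76.2 ± 6.24 to 21.8 ± 0.837 CPM (-1.80, adjusted p = 1.24e-10), Ces1d (-1.30), Epm2a (-1.28), Itgb2 (-1.15), Avil (-1.13) and Atp2a3 (-1.11). Actb, which encodes beta-actin, was at 2290 ± 94.9 and 2310 ± 75.4 CPM (adjusted p = 0.902). With 1 spread shared by all 14 libraries, 1520 genes were higher in CT26 and Epm2a (adjusted p = 0.0774) was no longer called.

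**Figure D1:**
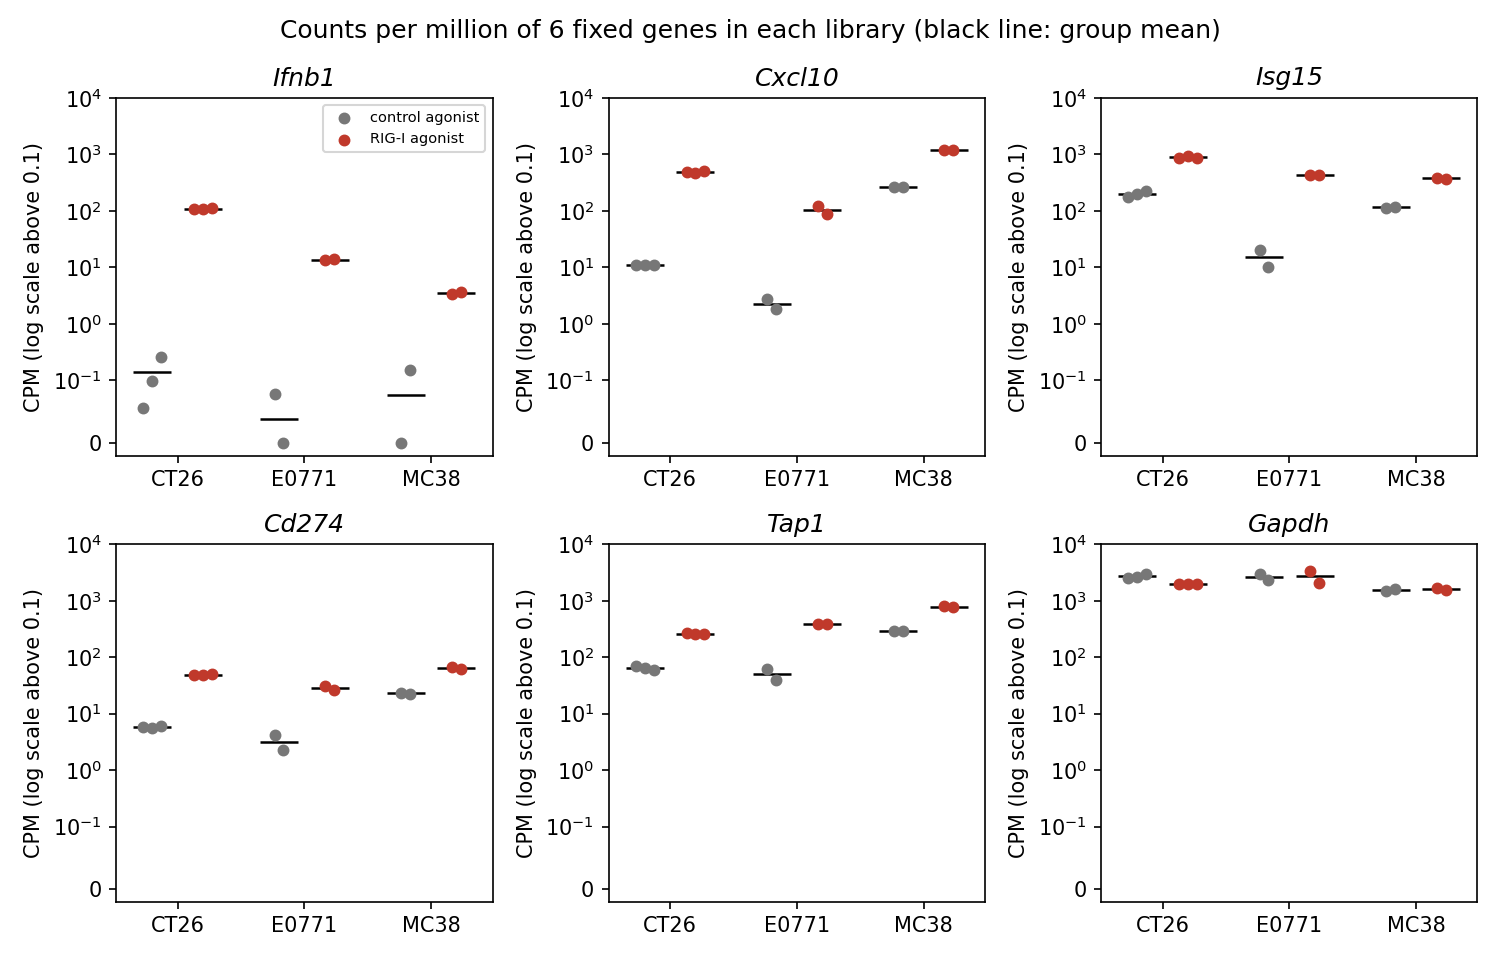
Levels of Ifnb1, Cxcl10, Isg15, Cd274, Tap1 and Gapdh in each library in CPM, on an axis that is logarithmic above 0.1, with control agonist in grey, RIG-I agonist in red and black lines at group means. Cxcl10 controls averaged 11.1 CPM in CT26, 2.27 in E0771 and 262 in MC38, against 489, 105 and 1190 with the RIG-I agonist.

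In E0771, antiviral transcripts such as Zbp1 and Ifit1 were higher with the RIG-I agonist, from low control levels (n = 2 libraries per agonist). Zbp1 rose from 0.322 ± 0.126 to 109 ± 12.6 CPM, 332-fold (log2 8.37, SE 0.27, adjusted p = 0.00277). Ifit1, which binds viral RNA, rose 47.8-fold from 12.5 ± 4.61 to 597 ± 63.1 CPM (adjusted p = 0.00469) and Isg15 28.7-fold from 15.3 ± 7.21 to 441 ± 0.523 CPM (adjusted p = 0.00761). Ifnb1 went from 1 count to 360, a ratio of 342 with an interval of 61.1 to 13600 (adjusted p = 0.00761), and Cxcl10 rose 45.9-fold from 2.27 ± 0.648 to 105 ± 23.9 CPM (adjusted p = 0.00469). Of 11728 genes tested, 180 were higher and 3 lower, while 1242 had an unadjusted p under 0.05. Of the called genes 179 higher and 2 lower ones changed at least 2-fold, and the median called change was 3.57 up and -1.27 down. Groups did not overlap in any of the 183 called genes. This held for 40.3% of all genes tested, where chance gives 33.3%.

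Of 54 antiviral genes measured in E0771, 48 rose, or 53 adjusted over the list alone, and none fell (median 3.39, adjusted p = 2.89e-270, and adjusted p = 0.105 with an estimated correlation). Their median level went from 15.8 to 185 CPM. Ifit3 rose by 6.59 from 1.55 ± 0.449 to 151 ± 8.54 CPM and Phf11d by 6.30, and Phf11b, a relative outside the list, by 7.06. Of 17 interferon-inducible GTPases, 16 rose, or 17 adjusted over the list alone (median 5.60, also with the bounded member at its bound, adjusted p = 5.48e-143, and adjusted p = 0.105 with an estimated correlation). Tgtp2 had no control counts and reached 18.3 ± 4.13 CPM, at least 153-fold higher, Iigp1 rose by 7.39 (SE 0.55), Tgtp1 by 6.60 and Gbp4 by 6.38. Single members share reads. Of 16 RNA-sensing genes, 8 rose, or 11 adjusted over the list alone (median 1.58, adjusted p = 1.22e-36, and adjusted p = 0.105 with an estimated correlation), including Irf7 at 5.43, Dhx58 at 3.71, Ifih1 at 3.37 and Ddx58 at 2.27 (adjusted p = 0.0447, and 0.13 or 0.151 without RIG-I replicate 1 or 2). Of 19 receptor, JAK, STAT, IRF and SOCS genes, 5 rose, or 10 adjusted over the list alone (median 0.58, adjusted p = 1.55e-16, and adjusted p = 0.105 with an estimated correlation), including Usp18 at 5.0. Of 10 DNA-sensing genes, 6 rose, or 7 adjusted over the list alone (median 1.90, adjusted p = 6.36e-28, and adjusted p = 0.131 with an estimated correlation), including Ifi205 at 7.21. Fewer than 3 interferon genes were tested. Ifna4 had no control counts and reached 4.88 ± 0.868 CPM, at least 40.7-fold higher (adjusted p = 0.03).

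Of 25 MHC class I genes in E0771, 11 rose, or 20 adjusted over the list alone (median 1.96, adjusted p = 1.28e-46, and adjusted p = 0.144 with an estimated correlation). Psmb10 rose by 3.60, the peptide-loading gene Tapbp by 3.31, Tap1 by 2.92 and Nlrc5 by 2.23, whereas H2-K1 was at 52.2 ± 26.2 and 297 ± 41 CPM (log2 2.51, adjusted p = 0.0614), H2-D1 at 1.61 (adjusted p = 0.127) and B2m at 1.57 (adjusted p = 0.211). Of 9 chemokine genes, 3 rose, or 7 adjusted over the list alone (median 4.13, or 4.07 with the bounded member at its bound, adjusted p = 6.36e-28, and adjusted p = 0.144 with an estimated correlation), including Ccl5 at 5.58 (SE 0.3). Of 29 cytokine and NF-kB target genes, 4 rose, or 21 adjusted over the list alone (median 1.72 with and without the bound, adjusted p = 1.69e-25, and adjusted p = 0.211 with an estimated correlation), including Tnfsf10 at 5.96 and the NF-kB subunit gene Relb at 1.92. Of 11 checkpoint ligand genes, 3 rose, or 4 adjusted over the list alone (median 0.94, adjusted p = 2.02e-06, and adjusted p = 0.144 with an estimated correlation). Cd274 rose by 3.14 from 3.21 ± 1.29 to 28.5 ± 2.49 CPM and Lgals9, which encodes galectin-9, by 2.14. Of 34 cell death genes, 3 rose, or 5 adjusted over the list alone (median 0.15, adjusted p = 0.00923, and adjusted p = 0.211 with an estimated correlation), including the death receptor gene Fas at 2.83 and Casp4 at 3.11, which was not called without RIG-I replicate 1 or 2 (adjusted p = 0.068 and 0.0563). Mlkl was at 1.08 (adjusted p = 0.171) and Casp8 at 0.36 (adjusted p = 0.496).

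Of 21 p53 targets in E0771, 1 rose on both adjustments (median 0.36, adjusted p = 0.00569, and adjusted p = 0.211 with an estimated correlation): Cdkn1a, which encodes the cell cycle inhibitor p21, went from 55.2 ± 3.48 to 150 ± 7.57 CPM (log2 1.44, adjusted p = 0.0119). Of 27 ER stress genes, 1, Atf3 (1.87), rose, or 3 adjusted over the list alone (median 0.10, adjusted p = 0.0224, and adjusted p = 0.376 with an estimated correlation). Lists that passed downward held no called gene on either adjustment, by edgeR. These were cell cycle (40 genes, median -0.16, adjusted p = 0.00183, and adjusted p = 0.693 with an estimated correlation), cholesterol biosynthesis (25 genes, -0.51, adjusted p = 0.0111, and adjusted p = 0.743 with an estimated correlation), and nuclear-encoded oxidative phosphorylation (32 genes, -0.18, adjusted p = 0.00333, and adjusted p = 0.211 with an estimated correlation). The 13 mitochondrially encoded genes had a median of -1.71 and no called gene (adjusted p = 8.37e-07, and adjusted p = 0.495 with an estimated correlation). mt-Co1 was at 11500 ± 1740 and 3860 ± 1310 CPM (adjusted p = 0.152). Their share of the counts was 2.82% and 5.8% in the control libraries and 0.81% and 2.21% in the RIG-I libraries. Without control replicate 1, p53 targets (adjusted p = 0.062), ER stress (0.328), cell cycle (0.142) and cholesterol biosynthesis (0.287, upward) did not pass. The same held for p53 targets without RIG-I replicate 1 (0.0773) and for ER stress (0.145), cell cycle (0.299) and cholesterol biosynthesis (0.719) without RIG-I replicate 2.

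The other 10 lists tested did not pass in E0771. MHC class II had 0 called of 3 genes, or 1 higher and 1 lower adjusted over the list alone. Its median of -0.07 and mean of 0.61 differed in sign and the test pointed up (adjusted p = 0.699). NK cell receptor ligands had 1 higher of 5, Clec2d (3.11, adjusted p = 0.0437, and 0.0597 or 0.084 without control replicate 1 or 2), or 1 and 1 adjusted over the list alone (0.07, adjusted p = 0.671). Immediate early genes had 0 called of 16 (0.31, adjusted p = 0.0673, and 0.00385 or 0.00245 without control replicate 1 or RIG-I replicate 2), MYC and ribosome biogenesis 0 of 26 (0.14, adjusted p = 0.138), glycolysis and hypoxia 0 of 23 (0.03, adjusted p = 0.849) and heat shock 0 of 10 (0.10, adjusted p = 0.849), all also 0 adjusted over the list alone. With the replicate number as a block, the immediate early list passed upward (adjusted p = 0.00116, and 0.398 with an estimated correlation). Extracellular matrix had 0 of 19, or 1 higher adjusted over the list alone (-0.09, adjusted p = 0.671). Epithelial genes (-0.17, adjusted p = 0.687), leukocyte markers (-0.65, adjusted p = 0.349) and endothelial markers (-0.46, adjusted p = 0.481) each had 0 called of 3 on both adjustments. Mki67 was at -0.70 (adjusted p = 0.191), Actb at 0.34 (adjusted p = 0.837) and Gapdh at 0.03 (adjusted p = 0.99).

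The lower genes of E0771 were S100a4, a calcium-binding protein gene linked to cell motility, from 97.8 ± 14.8 to 40.5 ± 2.67 CPM (-1.27, SE 0.16, adjusted p = 0.0343), Stmn1, which encodes a microtubule destabilizer, from 115 ± 6.19 to 59.9 ± 4.82 CPM (-0.95, adjusted p = 0.0491), and Gm45837 (-3.37, adjusted p = 0.0326), named after its values were seen. DESeq2 called 370 genes higher and 45 lower in E0771, and with 1 spread shared by all 14 libraries edgeR called 949 and 639. With the replicate number as a block edgeR called 1243 higher and 1215 lower, so the near absence of falls depends on the design. Dhx58 (adjusted p = 0.0658), Ddx58 (0.141) and Usp18 (0.145) were among the genes not called with the block. The labels do not say whether equal replicate numbers mark a pairing. Without RIG-I replicate 1 or 2 or control replicate 1 neither S100a4 (adjusted p = 0.0821, 0.0504 and 0.0563) nor Stmn1 (0.0962, 0.14 and 0.158) was called, and without control replicate 2 Stmn1 was not called (0.113) and 8 genes were lower. Stmn1 was also not called with RLE size factors (adjusted p = 0.0504).

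**Figure D2:**
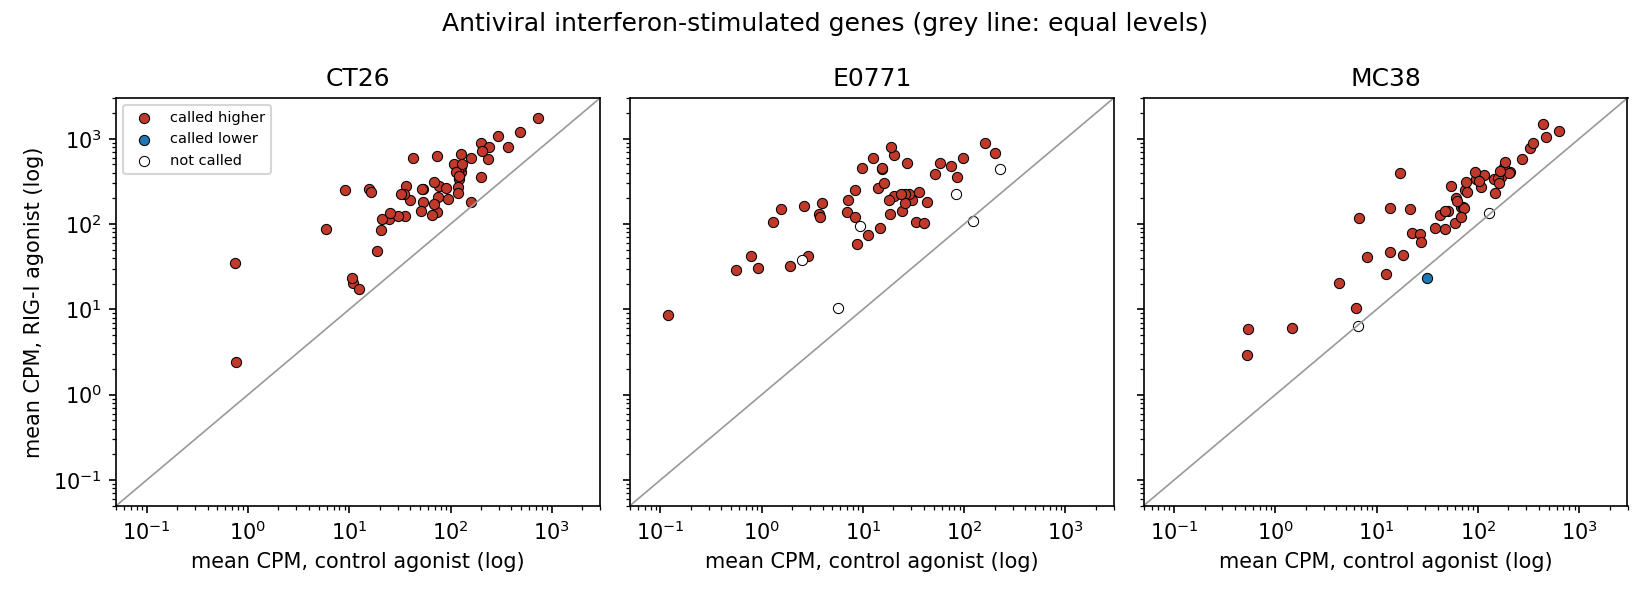
Mean CPM of each antiviral interferon-stimulated gene with control agonist (x axis) and RIG-I agonist (y axis), both logarithmic, with called genes in colour and a grey line at equal levels. The median went from 71 to 256 CPM in CT26, from 15.8 to 185 in E0771 and from 68.3 to 172 in MC38.

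In MC38, antiviral transcripts such as Ifit3 and Zbp1 were higher with the RIG-I agonist, from higher control levels than in E0771 (n = 2 libraries per agonist). Ifit3 rose from 17 ± 2.04 to 400 ± 2.97 CPM (log2 4.55, SE 0.06, adjusted p = 5.65e-23) and Zbp1 12-fold from 22.4 ± 0.324 to 269 ± 3.14 CPM (adjusted p = 3.23e-22). Cxcl10 rose 4.52-fold from 262 ± 0.157 to 1190 ± 3.07 CPM (adjusted p = 2.14e-21) and Cd274 2.82-fold from 22.8 ± 0.38 to 64.6 ± 3.41 CPM (adjusted p = 1.92e-13). Ifnb1 went from 2 to 111 counts, a ratio of 50.7 with an interval of 13.7 to 423 (adjusted p = 6.91e-08). Cyp51, an enzyme gene of cholesterol synthesis, fell from 932 ± 0.876 to 609 ± 13.5 CPM (-0.61, SE 0.03, adjusted p = 2.45e-12). Of 12387 genes tested, 2338 were higher and 2099 lower. At least a 2-fold change was seen for 252 and 128 of them, and the median called change was 0.28 up and -0.33 down. Groups did not overlap in any of the 4437 called genes, and in 67.2% of all genes tested, where chance gives 33.3%.

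Of 56 antiviral genes measured in MC38, 53 rose and 1, Ifitm1 (-0.42), which encodes a membrane protein that restricts virus entry, fell on both adjustments (median 1.35, adjusted p = 2.31e-249, and adjusted p = 0.0612 with an estimated correlation). Ifit3b rose by 4.14, Phf11d by 3.53, Slfn2 by 3.34, Ifit1 by 2.01 and Isg15 by 1.71 (SE 0.04, adjusted p = 1.3e-18). All 16 interferon-inducible GTPases rose on both adjustments (median 2.57, adjusted p = 5.41e-127, and adjusted p = 0.0694 with an estimated correlation), including Tgtp1 at 3.36 and Gvin1 at 3.35. Of 16 RNA-sensing genes, 10 rose and 1, the transcription factor gene Irf3 (-0.22), fell, or 11 and 2 adjusted over the list alone (median 0.57, adjusted p = 1.09e-32, and adjusted p = 0.0787 with an estimated correlation), including Irf7 at 2.58, Dhx58 at 2.57, Tlr3 at 1.58, Ifih1 at 1.06 and Ddx58 at 0.79. Of 3 interferon genes, 2 rose on both adjustments (median 3.93, adjusted p = 0.161). Of 18 receptor, JAK, STAT, IRF and SOCS genes, 11 rose and 1, Ifngr1 (-0.36), a chain of the interferon gamma receptor, fell, or 11 and 2 adjusted over the list alone (median 0.37, adjusted p = 2.67e-11, and adjusted p = 0.0797 with an estimated correlation). Usp18 rose by 1.78. Of 10 DNA-sensing genes, 8 rose, or 8 with 1 falling adjusted over the list alone (median 1.0, adjusted p = 3.16e-28, and adjusted p = 0.0797 with an estimated correlation), including Ifi205 at 4.37.

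Of 26 MHC class I genes in MC38, 21 rose and 1, Canx (-0.17), fell, or 22 and 1 adjusted over the list alone (median 0.86, adjusted p = 2.1e-49, and adjusted p = 0.0612 with an estimated correlation). H2-K1 rose by 0.82 from 1100 ± 24.7 CPM, H2-D1 by 0.85, B2m by 1.21, Tap1 by 1.43, Nlrc5 by 1.27, Psmb9 by 1.76 and Psmb10 by 1.62. MHC class II had 1 higher of 6 on both adjustments, Ctss (2.65), which encodes a protease of the class II pathway. Its median was -0.21, its mean 0.23 and the test pointed down (adjusted p = 0.985). Of 13 chemokine genes, 9 rose and 1, Cx3cl1 (-0.93), fell on both adjustments (median 0.93, adjusted p = 3.37e-14, and adjusted p = 0.0786 with an estimated correlation), including Cxcl11 at 4.67, Cxcl9 at 4.25, Ccl4 at 2.96 and Ccl5 at 1.47. Of 27 cytokine and NF-kB target genes, 20 rose on both adjustments (median 0.53, adjusted p = 1.52e-07, and adjusted p = 0.199 with an estimated correlation), including Tnfsf10 at 2.09 and Il15 at 1.31. Of 12 checkpoint ligand genes, 4 rose and 1, Tnfsf9 (-0.41), fell on both adjustments (median 0.17, adjusted p = 9.69e-05, and adjusted p = 0.132 with an estimated correlation), including Lgals9 at 1.56 and Cd47 at 1.01. NK cell receptor ligands had 1 higher and 2 lower of 6 on both adjustments, with Clec2d at 2.58 and Ulbp1 at -0.78. The median was -0.26, the mean 0.28 and the test pointed down (adjusted p = 0.94).

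Of 25 cholesterol biosynthesis genes in MC38, 24 fell and none rose on both adjustments (median -0.38, adjusted p = 2.53e-16, and adjusted p = 0.0765 with an estimated correlation). Beside Cyp51, falls were seen for Srebf2, which encodes the transcription factor that governs this pathway, from 664 ± 11.2 to 450 ± 10.2 CPM (-0.56), and for Dhcr7 (-0.54). Of 19 extracellular matrix and mesenchymal genes, 10 fell, or 11 adjusted over the list alone, and 2, the transcription factor genes Snai2 (0.80) and Twist1 (0.24), rose (median -0.29, adjusted p = 1.78e-05, and adjusted p = 0.132 with an estimated correlation). The collagen gene Col6a1 fell from 93 ± 1.48 to 37.1 ± 1.34 CPM (-1.33) and Fn1 by 0.63. All 13 mitochondrially encoded genes fell on both adjustments (median -0.71, adjusted p = 3.58e-25, and adjusted p = 0.132 with an estimated correlation), including mt-Nd1, a subunit gene of respiratory complex I, from 3770 ± 114 to 1590 ± 76.9 CPM (-1.24). Their share of the counts was 5.0% and 4.79% with control and 3.2% and 3.01% with RIG-I agonist. Nuclear-encoded oxidative phosphorylation had 1 higher and 3 lower of 32 on both adjustments (-0.04, adjusted p = 0.654). Of 23 glycolysis and hypoxia genes, 11 fell, or 12 adjusted over the list alone (median -0.08, adjusted p = 0.038, 0.0598 or 0.0653 without RIG-I replicate 2 or control replicate 1, and adjusted p = 0.298 with an estimated correlation), including Car9 at -1.57 and Egln3, an oxygen sensor gene, at -1.03. The 4 that rose were the hexokinase genes Hk1 (0.18) and Hk2 (0.29), the angiogenic factor gene Vegfa (0.15) and Ndrg1 (0.28).

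Of 26 MYC and ribosome biogenesis genes in MC38, 25 rose and 1, Cad (-0.10), fell on both adjustments (median 0.24, adjusted p = 1.67e-07, and adjusted p = 0.132 with an estimated correlation). Myc rose from 88.3 ± 2.79 to 150 ± 4.3 CPM (0.77). Of 29 ER stress genes, 23 rose and 2, Ddit4 (-0.11), an inhibitor of mTORC1, and Vldlr (-0.39), a lipoprotein receptor gene, fell on both adjustments (median 0.26, adjusted p = 1.4e-09, and adjusted p = 0.0787 with an estimated correlation), including Ddit3, which encodes CHOP, from 23 ± 1.34 to 56.5 ± 0.499 CPM (1.29), Chac1 at 1.01 and Trib3 at 0.99. Cell death had 11 higher and 6 lower of 33, or 13 and 6 adjusted over the list alone (0.09, adjusted p = 0.156), with Casp4 at 1.11 and Mlkl at 0.95. Casp8 was at 0.12 (adjusted p = 0.154). p53 targets had 7 higher and 4 lower of 21 on both adjustments (0.07, adjusted p = 0.227), with Eda2r at 1.04 and Cdkn1a at 0.11 (adjusted p = 0.239). Cell cycle had 3 higher and 11 lower of 40, or 4 and 12 adjusted over the list alone (-0.01, adjusted p = 0.257), and Mki67 fell by 0.47. Immediate early genes had 6 higher and 7 lower of 15 on both adjustments (-0.01, adjusted p = 0.0513), with Fosb falling by 1.43, Fos by 1.11 and Egr1 by 0.68. Heat shock had 1 higher and 3 lower of 10, or 2 and 3 adjusted over the list alone, with a median of 0.00 and a mean of -0.02 (adjusted p = 0.741). Epithelial genes (-0.37, adjusted p = 0.741) and leukocyte markers (-0.33, adjusted p = 0.675) had 0 called of 3 by edgeR on both adjustments, and endothelial markers 1 lower of 3, Egfl7 (-0.66), on both adjustments (-0.36, adjusted p = 0.636).

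Beyond the lists, Ms4a4d went from 2 to 330 counts in MC38, a ratio of 151 with an interval of 41.4 to 1250, and Ifi206, Ifi209 and Ifi207 rose by 5.24, 4.64 and 4.22. Among genes at a mean log2 CPM of at least 1, the largest falls included those of Ccnb1ip1, from 10.9 ± 2.5 to 1.87 ± 0.116 CPM (-2.56, SE 0.21, adjusted p = 3.96e-09), Cd38, an NAD-consuming ectoenzyme gene (-1.78), the water channel gene Aqp1 (-1.67), Fras1 (-1.60), Plat, which encodes tissue plasminogen activator (-1.39), and Trpc6 (-1.38, adjusted p = 0.009). Actb was at -0.05 (adjusted p = 0.225) and Gapdh at 0.03 (adjusted p = 0.584). DESeq2 called 1153 genes higher and 804 lower in MC38, and with 1 spread shared by all 14 libraries edgeR called 624 and 374, which ended the calls of H2-K1 (adjusted p = 0.0506), Gvin1 (0.0506), Snai2 (0.062), Cyp51 (0.523), Srebf2 (0.156), Dhcr7 (0.459), Col6a1 (0.182), mt-Nd1 (0.273), Fos (0.109), Fosb (0.0549), Aqp1 (0.194), Fras1 (0.291) and Trpc6 (0.105). Trpc6 was also not called with DESeq2 (adjusted p = 0.0686) or without RIG-I replicate 2 or control replicate 2 (0.0944 and 0.187).

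**Figure D3:**
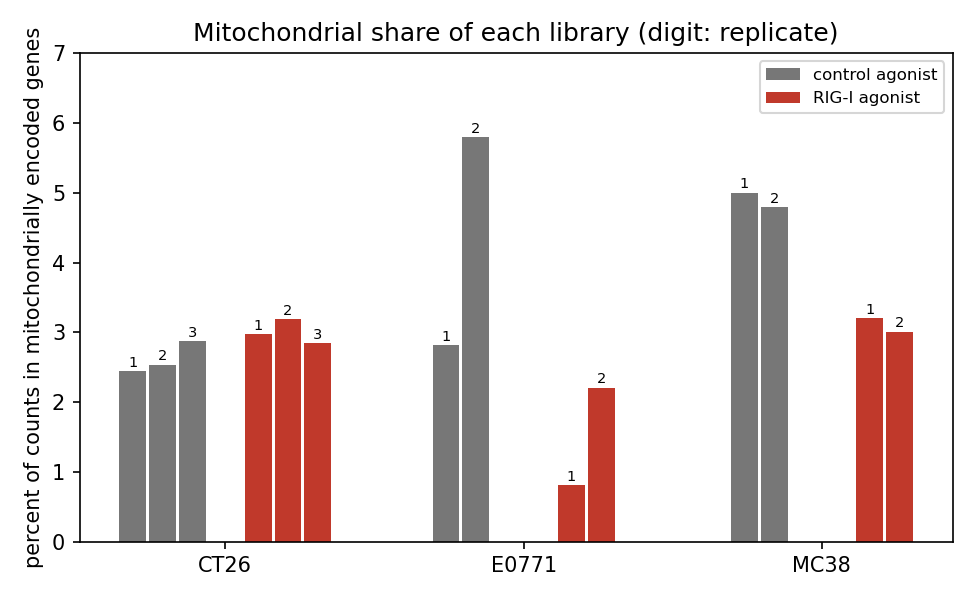
Percent of each library's counts in the 13 mitochondrially encoded genes, as bars from 0 for each replicate (digit), with control agonist in grey and RIG-I agonist in red. MC38 went from 5.0% and 4.79% to 3.2% and 3.01%, E0771 libraries ranged from 0.81% to 5.8%, and CT26 libraries from 2.44% to 3.19%.

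**Figure D4:**
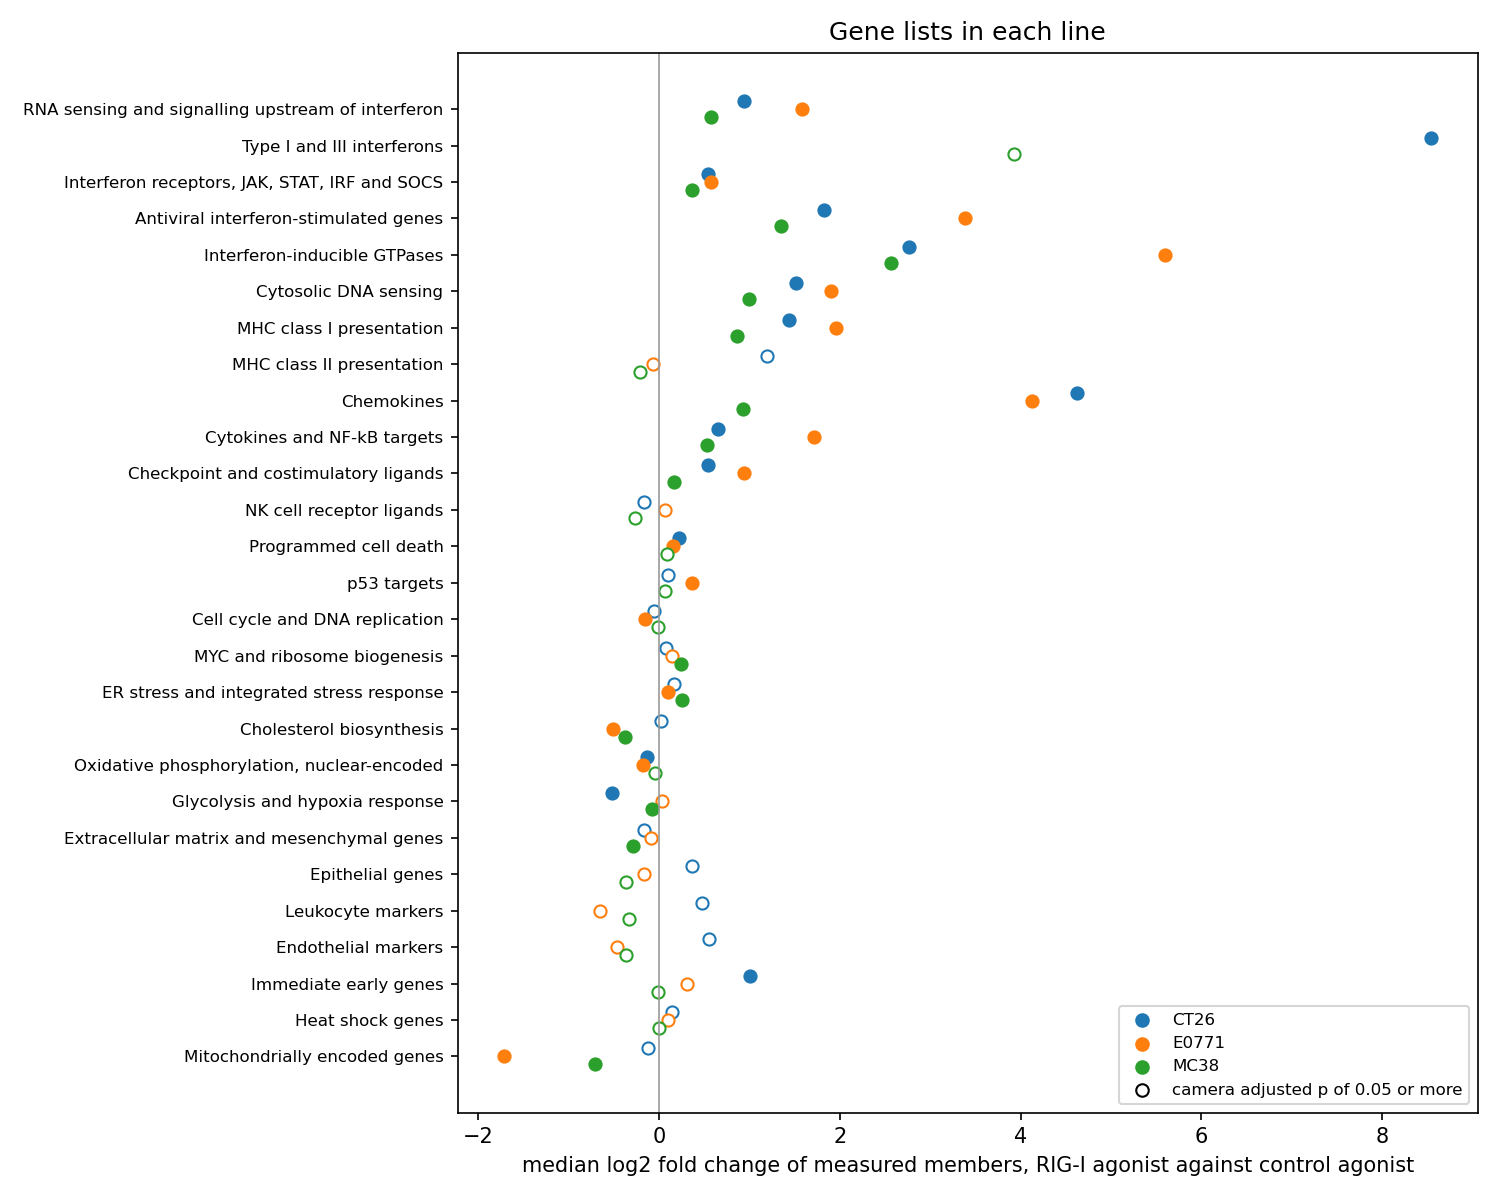
Median log2 fold change of the measured members of each gene list, RIG-I agonist against control agonist, in CT26 (blue), E0771 (orange) and MC38 (green), with open points where the camera adjusted p was 0.05 or more. The antiviral list was at 1.83, 3.39 and 1.35 and the cholesterol list at 0.02, -0.51 and -0.38.

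Over the lists, camera called 14 of 27 in CT26, 16 of 26 in E0771 and 15 of 27 in MC38. With the correlation estimated, 11 of the 14 held in CT26, and none in E0771 or MC38, where camera with the preset correlation gave 16 and 15 and fry gave 10 and 21. The estimate was not always above the preset correlation. In MC38 it was -0.022 for cholesterol biosynthesis (adjusted p = 2.53e-16 preset, 0.0765 estimated) and -0.086 for checkpoint ligands (9.69e-05 and 0.132). Such losses do not show correlated members, since that run also had only 2 residual degrees of freedom there.

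The higher genes overlapped between lines. Among 10690 genes tested in all 3 lines, 173 of the 174 higher in E0771 were also higher in CT26, against 33.7 from independent lists, and 167 of the 174 were higher in MC38, against 35.9. CT26 and MC38 shared 932 of 2072 and 2207 higher genes, against 427.8, and 870 of 2279 and 1820 lower genes, against 388. 135 genes were higher in CT26 and lower in MC38 and 162 the reverse. In all 3 lines 167 genes were higher, 73 of them in the antiviral, GTPase or MHC class I lists, and 1, S100a4, was lower (-0.90, -1.27 and -0.53 in CT26, E0771 and MC38; not called in E0771 without RIG-I replicate 1 or 2 or control replicate 1, adjusted p = 0.0821, 0.0504 and 0.0563). No controls were shared between lines. Across the 10690 genes, which are not independent replicates, log2 fold changes correlated with Pearson's r of 0.68 for CT26 with E0771, 0.55 for CT26 with MC38 and 0.67 for E0771 with MC38, and with Spearman's rho of 0.48, 0.37 and 0.45.

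Whether the agonist effect differed between lines was tested as an interaction over 14657 genes. The column names of E0771 and MC38 share a prefix that those of CT26 lack, so CT26 may have been handled apart. Differences of CT26 from the other lines cannot be told apart from a difference between such experiments. CT26 and E0771 differed in 568 genes, with the change more positive in CT26 for 156 and in E0771 for 412. Zbp1 had the larger log2 fold change in E0771 (difference CT26 minus E0771 of -4.98, SE 0.23, adjusted p = 2.59e-07), as did Irf7 (-2.96), Isg15 (-2.73), Ifit1 (-2.54), Dhx58 (-1.39) and Cdkn1a (-1.34). With the RIG-I agonist Zbp1, Irf7 and Isg15 stood at 109, 481 and 441 CPM in E0771 and at 513, 1020 and 890 in CT26. Ifit1, Dhx58 and Cdkn1a stood at 597, 130 and 150 against 623, 149 and 238 CPM. Control levels of all these genes were lower in E0771. Krt16 (6.93, SE 0.92, adjusted p = 0.000542), the cation channel gene Trpc1 (5.04, SE 0.78, adjusted p = 0.00116), Ccl4 (4.61, adjusted p = 0.0227) and Acod1 (4.0, adjusted p = 0.0188) had the more positive effect in CT26. Trpc1 went from 1 to 53 counts there and stood at 7.07 and 7.44 CPM in E0771. With the RIG-I agonist Krt16 stood at 14.3 CPM in CT26 and 13.9 in E0771, and Acod1 at 14.9 and 13.6. Their controls held 1 count each in CT26 and stood at 1.65 and 0.201 CPM in E0771. Ccl4 reached 44.6 CPM in CT26 and 5.06 in E0771. The kinase-like gene Adck1 differed the other way (-4.62, SE 0.66, adjusted p = 0.00116), from 1 to 27 counts in E0771, a ratio of 25.7 with an interval of 4.23 to 1050, against 19 ± 1.51 and 18 ± 0.403 CPM in CT26. Tgtp2 was at 17.4 and 76.9 CPM in CT26 against 0 and 18.3 in E0771, and Kalrn at 12.6 and 12.2 against 0 and 1.13. Of the lists, the GTPases (median difference -3.39, adjusted p = 5.62e-67), antiviral genes (-1.32, adjusted p = 5.73e-116), RNA sensing (-0.48), DNA sensing (-0.44) and the receptor, JAK, STAT, IRF and SOCS genes (-0.18) differed with the preset and the estimated correlation. Ccl4 was not called without CT26 control replicate 1 or E0771 control replicate 1 or 2 (adjusted p = 0.0504, 0.145 and 0.1), nor Acod1 without CT26 control replicate 2 or 3 or E0771 control replicate 2 (0.0643, 0.0546 and 0.172). The count of genes was 349 and 358 without CT26 RIG-I replicate 1 or 2 and 863 without E0771 RIG-I replicate 1, and Man1c1 and Fam71f1, which the naming rule also took, lost their calls without several single libraries.

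CT26 and MC38 differed in 557 genes, with the change more positive in CT26 for 290 and in MC38 for 267. The log2 fold change was larger in CT26 for Ccl5 (4.90, adjusted p = 2.9e-07), Cxcl10 (3.23, adjusted p = 2.9e-07), Cd274 (1.52, adjusted p = 0.000294), Ifih1 (1.15) and Ifit1 (1.01). The same held for Acod1 (7.69, SE 0.62, adjusted p = 1.94e-05), Krt16 (8.46, SE 1.18) and Ccl4 (5.77, SE 0.75). With the RIG-I agonist Cxcl10 and Cd274 stood at 489 and 49.1 CPM in CT26 and at 1190 and 64.6 in MC38. Their controls stood at 11.1 and 5.83 against 262 and 22.8 CPM. The other genes named here stood higher in CT26 than in MC38 with the RIG-I agonist, such as Ccl5 at 152 against 56 CPM. Angptl6, an angiopoietin-like factor gene, differed the other way (-2.39, SE 0.2, adjusted p = 4.73e-05), falling from 27 ± 2.33 to 12.7 ± 1.05 CPM in CT26 and rising from 4.14 ± 0.22 to 9.89 ± 0.972 in MC38, as did the laminin gene Lama3 (-1.84, adjusted p = 0.00456, and 0.0536 without MC38 control replicate 1). The chemokine (median difference 1.97, adjusted p = 2.73e-40) and immediate early lists (1.14, adjusted p = 5.37e-24) differed with both correlations, whereas the antiviral list (0.31, adjusted p = 5.8e-13) had an adjusted p = 0.259 with an estimated correlation. The count was 362 without CT26 control replicate 2, 285, 293 and 338 without CT26 RIG-I replicate 1, 2 or 3, 181 and 183 without MC38 control replicate 1 or 2, and 187 and 167 without MC38 RIG-I replicate 1 or 2. Ifna4, Ifi44l, Htatip2, Mgarp and Smpdl3b, which the naming rule also took, lost their calls without several single libraries.

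E0771 and MC38 differed in 309 genes, with the change more positive in E0771 for 265 and in MC38 for 44. The change was more positive in E0771 for Zbp1 (4.80, SE 0.25, adjusted p = 3.17e-07), Ccl5 (4.08), Ifit1 (3.55, adjusted p = 6.38e-06), Cxcl10 (3.33, adjusted p = 3.46e-06), Isg15 (3.13, adjusted p = 7.76e-05), Irf7 (2.83), Ifih1 (2.30), H2-K1 (1.68, adjusted p = 0.0194, though its change within E0771 was not called, adjusted p = 0.0614), Cd274 (1.62), Tap1 (1.48), Ddx58 (1.47), Cdkn1a (1.31) and Nlrc5 (0.96). Cxcl10, H2-K1, Zbp1, Tap1, Cd274 and Ddx58 nevertheless stood lower in E0771 than in MC38 with the RIG-I agonist. Cxcl10 was at 105 against 1190 CPM, H2-K1 at 297 against 1930 and Cd274 at 28.5 against 64.6. The others of these genes stood higher in E0771, such as Ccl5 at 113 against 56 CPM. Control levels of all of them except Cdkn1a were lower in E0771. Adck1 also differed (4.66, SE 0.67, adjusted p = 0.00132), at 24 ± 0.92 and 21.5 ± 0.305 CPM in MC38, and Kalrn stood at 10 and 9.41 CPM there. Hid1, a gene of secretory granule sorting, differed the other way (-1.93, SE 0.19, adjusted p = 7.72e-05), at 8.1 and 4.46 CPM in E0771 and 35.2 and 73.2 in MC38, as did Cd14 (-1.36, adjusted p = 0.00326), which encodes a receptor for bacterial lipopolysaccharide, at 1.99 and 1.41 against 21.1 and 38 CPM. Lists that differed with both correlations were GTPases (median difference 3.00, adjusted p = 2.3e-83), chemokines (2.40), antiviral genes (1.77, adjusted p = 2.41e-203), cytokines (1.23), MHC class I (1.07), DNA sensing (0.89), RNA sensing (0.85), checkpoint ligands (0.41) and the receptor, JAK, STAT, IRF and SOCS genes (0.39). The count was 166 without MC38 control replicate 1 or 2, 171 and 179 without MC38 RIG-I replicate 1 or 2, and 476 and 477 without E0771 control replicate 1 or RIG-I replicate 2. Cd14 was not called without E0771 control replicate 1 (adjusted p = 0.0688), and Ido2, Ifi213, Dusp28 and Htatip2, which the naming rule also took, lost their calls without several single libraries.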

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

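The comparisons between lines were planned, as were the tests of depth, of low control counts and of GC content, whereas the tests of a shared spread, of levels with either agonist, of untreated libraries, of nuclear-encoded oxidative phosphorylation genes, of the mitochondrial share and of other splits were chosen only after the result was seen.

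The effect of the RIG-I agonist differed between the lines, tested as an interaction in edgeR, for 568 genes between CT26 and E0771, 557 between CT26 and MC38 and 309 between E0771 and MC38. The genes and lists named here were singled out because this difference passed its test, and for each gene the pair of lines with the largest difference is given. For CT26 minus E0771 the log2 difference was -4.98 for Zbp1, -2.96 for Irf7, -1.39 for Dhx58 and -1.34 for Cdkn1a. For CT26 minus MC38 it was 4.90 for Ccl5. For E0771 minus MC38 it was 3.55 for Ifit1, 3.33 for Cxcl10, 3.13 for Isg15, 2.30 for Ifih1, 1.68 for H2-K1, 1.62 for Cd274, 1.48 for Tap1, 1.47 for Ddx58 and 0.96 for Nlrc5. Of the gene lists, the median difference for CT26 minus E0771 was -3.39 for interferon-inducible GTPases, -1.32 for antiviral genes, -0.48 for RNA sensing, -0.44 for cytosolic DNA sensing and -0.18 for interferon receptors with JAK, STAT, IRF and SOCS genes. For CT26 minus MC38 it was 1.97 for chemokines and 1.14 for immediate early genes. For E0771 minus MC38 it was 3.00 for GTPases, 2.40 for chemokines, 1.77 for antiviral genes, 1.23 for cytokines and NF-kB targets, 1.07 for MHC class I, 0.89 for cytosolic DNA sensing, 0.85 for RNA sensing, 0.41 for checkpoint ligands and 0.39 for interferon receptors with JAK, STAT, IRF and SOCS genes. These lists passed camera with the preset and with the estimated correlation. Within E0771 or MC38 alone no list passed with the estimated correlation. The fit of all 14 libraries has a smaller spread than E0771 alone. The list differences were not rerun with single libraries left out or with the replicate number as a block. CT26 may have been handled apart from the other lines, so its differences from them cannot be told apart from a difference between experiments.

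E0771 had 183 called genes, against 5334 in CT26 and 4437 in MC38. Lower depth was argued against as the whole cause: CT26 libraries thinned to the E0771 depths, 2 against 2, still gave at least 2031 called genes over 9 choices of libraries. With 1 spread shared by all 14 libraries E0771 had 1588 called genes, so the larger spread between its replicates may account for part of the low count, although that fit also had more residual degrees of freedom and tested more genes. With the replicate number as a block, the fit of E0771 alone gave 1243 higher and 1215 lower genes. Deviations of equally numbered libraries from their group correlated at 0.76 there. The labels do not say that equal numbers mark a shared culture or day, so a pairing stays unknown. A biological difference between the lines was not tested and stays open.

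Antiviral genes had larger log2 fold changes in E0771 than in MC38, with a median difference of 1.77. With the RIG-I agonist the list stood at about the same level in both lines (median log2 difference -0.05, interquartile range -0.6 to 0.21), whereas its control level was lower in E0771 (-2.29, -3.39 to -1.16), for 52 of 56 members. The larger folds may thus reflect the control levels. Low counts were argued against, since 32 members at 10 CPM or more in the controls of both lines had a median difference of 1.53 (0.97 to 2.34). Whether the control agonist itself raised these genes in MC38 cannot be told apart from a high resting level with 0 untreated libraries, and a difference in biology between the lines was not tested.

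All 13 mitochondrially encoded genes were lower with the RIG-I agonist in MC38, with a median log2 fold change of -0.71. Low GC content was argued against: 353 nuclear genes in the same range of 31.9% to 41.1% GC had a median of 0.03 (-0.09 to 0.13). A fall of oxidative phosphorylation transcripts as a whole was argued against by the nuclear-encoded list, with a median of -0.04. Variation of the mitochondrial share between libraries, unrelated to the agonist, cannot be told apart from an effect of the agonist: 2 libraries per agonist give an exact permutation p of 0.333 at best, which was reached. Replicates with the same agonist differed 1.04-fold and 1.06-fold in this share in MC38 and 2.06-fold and 2.73-fold in E0771.

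The 6 CT26 libraries can be split into 10 ways of 3 against 3, too few for a share under 0.05. Only 1 of the 10 splits, the real one, gave as many higher genes, 2751 against at most 1 in another split, and only 1 of 10 gave as many lower genes, 2583 against at most 1. For gene lists past the threshold by camera at the preset correlation, 3 of the 10 splits gave 14 or more. The real split gave 14, the highest other 14 and the lowest other 9. All other splits mix both agonists in each group. The agonist effect then enters the spread within groups, so low counts of called genes there follow from the design. Their groups still differ in the number of RIG-I libraries, so their lists are not counts without an agonist effect.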

How the results depend on the processing

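Leaving out mitochondrially encoded genes, leaving out libraries in the list tests, and the block with an estimated correlation were chosen only after the result was seen. No gene called in a line changed sign under any alternative. Size factors by RLE and the stricter filter kept all counts of genes within 1.5 times, as did leaving out mitochondrial genes for the counts per line, where alone it was run. The median log2 fold change of all genes in a line stayed between -0.051 and 0.01. Among results for the genes the naming rule took, 59 became stronger, 185 weaker and 0 reversed. Among results for lists, 18 became stronger, 91 weaker and 1 reversed: the E0771 cholesterol list pointed up without control replicate 1 (adjusted p = 0.287), and ranged over its alternatives from 2.1e-18 to 0.743, with 2.1e-18 without control replicate 2 and 0.719 without RIG-I replicate 2.

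In CT26, 1 fit of all 14 libraries gave 1520 higher genes, and fry put 23 lists past the threshold. In E0771, DESeq2 gave 370 higher and 45 lower genes, no filter 22 lower, and 1 fit of all libraries 949 and 639. Camera with an estimated correlation gave 0 lists there, where the preset one gave 16, and fry 10. In MC38, DESeq2 gave 1153 and 804 genes, 1 fit of all libraries 624 and 374, and the estimated correlation 0 lists against 15. DESeq2 gave 1020 genes for CT26 against MC38 and 499 for E0771 against MC38. The joint fit used a larger spread than MC38 alone and a smaller one than E0771 alone (common dispersion 0.0149 against 0.000927 and 0.041); otherwise the cause was not tested.

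Deviations of libraries with equal replicate numbers from their group correlated at 0.76 across 9320 genes in E0771 and at 0.08 in MC38. In CT26 they correlated at 0.07 to 0.19, where control replicate 1 correlated more with RIG-I replicate 2 (0.1) than with its own number. With 2 libraries per agonist, unequal numbers must give the same value with the opposite sign, -0.76 in E0771. The genes are not independent replicates, so this value cannot decide on a pairing. With the number as a block, E0771 had 1243 higher and 1215 lower genes, sharing 156 of the 183 calls, and the share of higher genes went from 98.4% to 50.6%. Ddx58, Dhx58 and Usp18 were among the genes called in E0771 without the block and not with it. With the block and an estimated correlation together, 3 lists passed in CT26, 0 in E0771 and 0 in MC38, against 14, 17 and 15 with the block and the preset correlation. The block gave 1537 genes for CT26 against E0771, 1816 for CT26 against MC38 and 880 for E0771 against MC38, and the cause was not tested.

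Leaving out 1 library gave 2060 to 2983 higher and 1803 to 2924 lower genes in CT26, 159 to 212 higher and 2 to 8 lower in E0771 (8 without control replicate 2), and 1867 to 2064 higher and 1566 to 1753 lower in MC38. Of the genes the naming rule took, those no longer called without 1 library numbered 3 to 6 in CT26, 4 and 5 without E0771 control replicate 1 or 2, 11 and 12 without E0771 RIG-I replicate 1 or 2, and 6 to 11 in MC38. The difference between CT26 and E0771 held 349 to 863 genes: 349 and 358 without CT26 RIG-I replicate 1 or 2 and 863 without E0771 RIG-I replicate 1. That between CT26 and MC38 held 167 to 506: 362 without CT26 control replicate 2, 285, 293 and 338 without CT26 RIG-I replicate 1, 2 or 3, 181 and 183 without MC38 control replicate 1 or 2, and 187 and 167 without MC38 RIG-I replicate 1 or 2. That between E0771 and MC38 held 166 to 477: 476 and 477 without E0771 control replicate 1 or RIG-I replicate 2, 166 without MC38 control replicate 1 or 2, and 171 and 179 without MC38 RIG-I replicate 1 or 2. Fewer samples entered these fits, and where 1 sample was left in a group its spread was taken from the other groups; otherwise the cause was not tested. A count of 0 allowed up to 0.0262 CPM over a group in CT26, 0.12 in E0771 and 0.105 in MC38, which limits folds of genes absent from the controls.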

Other observations

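Apart from Ccrl2 and Ifi27 in CT26, the genes in this part were chosen after their values were seen. Several genes outside the 27 lists were called higher in all 3 lines by edgeR. Sp110, a nuclear body protein gene, had log2 fold changes of 2.54, 3.49 and 2.10 in CT26, E0771 and MC38, Batf2, a transcription factor gene, of 2.90, 6.13 and 2.43, and the surface antigen gene Ly6a of 3.80, 4.06 and 3.10. Ccrl2 rose by 6.55, 5.16 and 2.86, and Slfn8, of the schlafen family, by 2.56, 3.79 and 2.36. Smaller rises were those of Shisa5, a gene of p53-dependent death (0.91, 1.40 and 1.22), and Ogfr, the opioid growth factor receptor gene (0.83, 1.09 and 0.81).

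Ifi27, named for its induction by interferon, was lower with the RIG-I agonist in CT26 (76.2 and 21.8 CPM, log2 -1.80, adjusted p = 1.24e-10) and MC38 (179 and 76.9 CPM, -1.23, adjusted p = 3.75e-14), and stood at 50.9 and 21.6 CPM in E0771 (-1.24, adjusted p = 0.225). Its relative Ifi27l2a, a member of the antiviral list, had a higher mean with the RIG-I agonist in every line. It stood at 199 and 360 CPM in CT26 and at 1.46 and 5.98 in MC38. In E0771 it was at 2.5 ± 1.09 and 37.7 ± 34.9 CPM.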
